A study of Homo sapiens with 4 samples.

How the data were processed

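Polyadenylated RNA was sequenced as paired-end reads from the cytoplasmic and the nuclear fraction of mouse embryonic stem cells. The series holds 4 libraries, 2 per fraction. Per the labels' protocols, cells grown in 2i and LIF medium were swollen and lysed with a mild detergent to give the cytoplasmic fraction, nuclei were purified through sucrose, and libraries were made with a TruSeq RNA kit after DNase treatment. The groups were taken from the sample titles. The labels name the organism as human while the cell type, the series design and every identifier in the deposited table are those of mouse, so the samples are treated here as mouse cells.

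The deposited table gives 1 value per row and library, in 130402 rows. Its identifier column mixes 33693 Ensembl gene identifiers, called gene rows here, with 96709 Ensembl transcript identifiers, called transcript rows. Per the submitters' processing notes the tools were Bowtie2 2.2.5, TopHat2 2.0.14, Cufflinks and Cuffdiff 2.2.1, and the genome build named there is hg19, a human build that does not go with the mouse identifiers. The annotation release and the mouse build are not given in the sources used here. The values were read as FPKM (fragments per kilobase of feature, divided by library size) as the authors deposited them, because Cuffdiff is named and the values are fractional with many tiny nonzero estimates. The file header names only the samples, so the unit is an inference. How the authors scaled libraries against each other is not stated. What a gene row measures is not stated either. Gene rows are not gene totals, since they summed to between 20642 and 25114 FPKM per library against 337923 to 621462 FPKM in transcript rows.

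No read count per row is given, so the depth of each library is unknown and no interval from read counts is reported. Among gene rows under 0.05 FPKM, the ratio between replicates had a sharp mode. At that mode the FPKM value was 1.07 times as large in cytoplasm replicate 2 as in replicate 1 (294 rows against at most 97 in any other bin) and 1.14 times as large in nucleus replicate 2 as in replicate 1 (236 rows against at most 93). No clear mode was found between the fractions. Such modes would arise if the same few reads were divided by different library sizes, which was not tested. An exact 0 in such a table can be a failed estimate of an isoform. 32296 rows were at 0 in all 4 libraries.

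Transcript rows and gene rows were each fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.1), nucleus against cytoplasm, with moderated variances that follow a trend in abundance. Rows with a mean of at least 1 FPKM over the 4 libraries were tested, which left 2669 gene rows and 25081 transcript rows. Calls had a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each class. Fold changes are on the log2(FPKM + 0.1) scale, which understates the change of low rows. The difference between the classes was tested with camera in a joint fit (preset correlation 0.01). Summaries used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The fits were tested on simulated data with 200 changed rows per class. In the gene row simulation of 2669 rows, 100% of rows changed by 1 log2 unit were recovered and 13 unchanged rows were called. In the transcript row simulation of 25081 rows, 60% of rows changed by 1 log2 unit and 83% of those changed by 2 were recovered, and 8 unchanged rows were called. Simulated noise was normal, with a spread smoothed over rows of like abundance, and far fewer rows changed than were called in the data. These rates therefore do not measure recovery or false calls in the data.

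The design, the gene lists and most alternatives were fixed before the data were examined, and the closing section names the alternatives added later. They assumed gene symbols and a link from transcripts to genes. The deposited table pairs no identifier with a symbol, a gene class or a parent gene, and 0 of its identifiers were found in the name tables at hand, which are human. The gene lists, the comparison of lncRNAs with mRNAs, gene values summed over isoforms and the test of isoforms within a gene were therefore not analysed here, and the deposited gene rows took the place of gene values. The naming rule needed symbols. In its place the text names, by identifier, the gene row and the transcript row with the largest change in each direction among called rows with a mean of at least 5 FPKM whose 2 fractions did not overlap. The comparison of gene rows with transcript rows was added after the table was seen.

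The replicate numbers recur in both fractions, but the labels do not say that a number marks one culture. No block was therefore used. Nothing states that the replicates came from separate cultures, so p-values measure the spread between these libraries only, which may be technical. The alternatives were other pseudocounts, filters and scalings, a fit without the variance trend, a replicate block, a minimum fold change and leaving out each library.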

Results

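RNA abundance was measured in the cytoplasm and in the nucleus of mouse embryonic stem cells, the self-renewing cells of the early embryo kept in culture. The series asked how RNA is divided between the fractions, within a study that contrasts lncRNAs with mRNAs. Each fraction was represented by 2 libraries of polyadenylated RNA. FPKM values are relative to library size, and no amount of RNA per fraction was used here. A row called higher in a fraction therefore has a higher relative level there. That does not give the share of its molecules in that fraction. The table held estimates for 33693 gene identifiers and 96709 transcript identifiers, with no symbols, so the results below concern these classes of rows and not named genes. Replicates were close to each other and the fractions were far apart. Over tested transcript rows the correlation of log2 values was 0.94 between cytoplasmic replicates and 0.93 between nuclear replicates, against 0.48 to 0.51 between fractions. For gene rows it was 0.98 within each fraction and 0.44 to 0.48 between them. These correlations run across rows, which are not independent replicates.

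Nuclear libraries had more rows of both classes at 1 FPKM or more than cytoplasmic libraries, with the larger ratio among gene rows. The number of gene rows at 1 FPKM or more was 4176 ± 26.9 in the nucleus and 536.5 ± 10.6 in the cytoplasm (SD, n = 2), a ratio of 7.78. Transcript rows at that level numbered 24943 ± 150 in the nucleus and 21657 ± 51.6 in the cytoplasm (SD, n = 2), a ratio of 1.15. Cytoplasmic RNA was concentrated in fewer transcripts. The most abundant transcript rows that together held 50% of transcript FPKM numbered 458 ± 5.66 in the cytoplasm and 1210 ± 17.7 in the nucleus, and the 100 most abundant transcript rows held 30.3% ± 0.192 and 21.7% ± 0.134 (SD, n = 2 for each value). Summed FPKM differed as well, at 640780 ± 1871 in the cytoplasm and 363595 ± 790 in the nucleus. With 2 libraries against 2, an exact two-sided permutation test cannot give a p under 0.333, so these values are set only against the spread between replicates, which was far smaller than each difference.

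**Figure D1:**
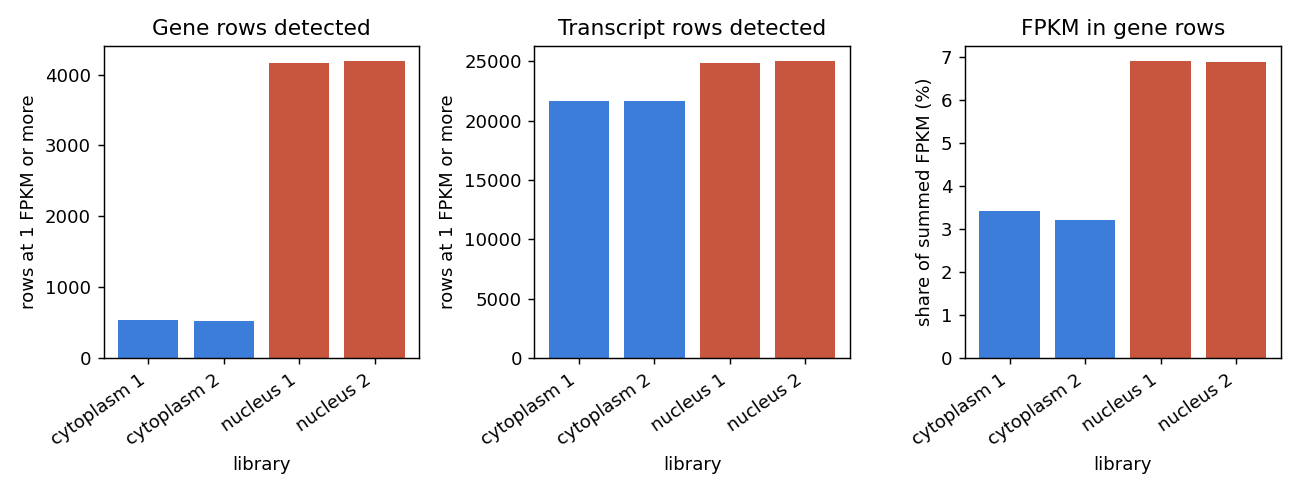
Gene rows and transcript rows at 1 FPKM or more (rows per library) and the share of summed FPKM in gene rows (percent), with 1 bar per library and the cytoplasm in blue, the nucleus in red. Both nuclear libraries show 4157 and 4195 gene rows at this level, against 529 and 544 in the cytoplasmic libraries.

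Gene rows lay mostly on the nuclear side. Of 2669 gene rows tested, 2451 (91.8%) were higher in the nucleus and 158 (5.92%) were higher in the cytoplasm by limma with adjusted p under 0.05, and 60 did not pass. The median called nuclear row was 9.08-fold higher in the nucleus, and the median called cytoplasmic row was 2.63-fold higher in the cytoplasm. With a pseudocount of 1 these folds were 3.32 and 2.13. The rows higher in the cytoplasm were the more abundant ones, with a median of 4.60 FPKM against 1.93 FPKM for those higher in the nucleus (4.16 against 2.55 FPKM after scaling to the mean FPKM total). Among gene rows of 1 to 3 FPKM, 94.8% were higher in the nucleus and 3.30% in the cytoplasm. Among the 33 gene rows of 30 to 100 FPKM these shares were 60.6% and 36.4%. The median standard error of a gene row's log2 difference was 0.11. When each library was centred on the median of its own gene rows, which sets the middle gene row near 0, the calls were 1050 higher in the nucleus and 805 in the cytoplasm, and quantile normalization gave 1134 and 774. Centring on transcript rows left them at 2444 and 167. With no filter on low values, 14080 of 22719 gene rows were higher in the nucleus and 377 in the cytoplasm, and the median log2 difference was 0.57. Far more gene rows reached 1 FPKM in the nucleus than in the cytoplasm, so the filter on the mean admitted them mostly through their nuclear values. The 91.8% and the 9.08-fold median therefore hold for rows chosen by that filter.

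The gene row with the largest nuclear excess was ENSMUSG00000018379.15, at 79.9 ± 8.74 FPKM in the nucleus and 0.907 ± 0.0426 FPKM in the cytoplasm (SD, n = 2). Its log2 difference was 6.31 with a standard error of 0.12 (limma, adjusted p = 9.4e-07), and it was 3.34 with libraries centred on their gene row medians and 4.85 with quantile normalization. The gene row with the largest cytoplasmic excess was ENSMUSG00000074748.3, at 14.3 ± 2.42 FPKM in the cytoplasm and 0.0287 ± 0.0025 FPKM in the nucleus (SD, n = 2), a log2 difference of -6.80 with a standard error of 0.14 (limma, adjusted p = 9.4e-07). The nuclear level of the latter lies under the pseudocount, and with a pseudocount of 1 its log2 difference was -3.89. With libraries centred on their gene row medians it was -9.77.

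Gene rows took 6.90% ± 0.0247 of summed FPKM in the nucleus and 3.32% ± 0.150 in the cytoplasm (SD, n = 2; exact permutation p = 0.333, the smallest possible). A few abundant gene rows held most of the cytoplasmic share. The 10 most abundant gene rows, ranked by the mean over all libraries, summed to 16152 ± 798 FPKM in the cytoplasm and 4237 ± 682 FPKM in the nucleus. Without these 10 gene rows the share was 5.80% ± 0.156 in the nucleus and 0.821% ± 0.0197 in the cytoplasm (SD, n = 2), a ratio of 7.07. That ranking favours rows high in the cytoplasm, where FPKM totals are larger. Ranked on the nuclear libraries alone, a choice made after seeing the data, leaving out 10 gene rows gave 5.73% ± 0.150 and 1.08% ± 0.0260 (SD, n = 2), a ratio of 5.31.

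Transcript rows were split between the fractions. Of 25081 transcript rows tested, 7509 (29.9%) were higher in the nucleus and 11197 (44.6%) were higher in the cytoplasm by limma with adjusted p under 0.05, and 6375 did not pass. The median change of called rows was larger on the nuclear side, at 7.14-fold, than on the cytoplasmic side, at 2.84-fold. With a pseudocount of 1 these folds were 3.25 and 2.37. Transcript rows higher in the cytoplasm were also more abundant, with a median of 8.56 FPKM against 3.44 FPKM as deposited, and 8.13 against 4.44 FPKM after scaling to the mean total. The middle transcript row lay at a log2 difference of -0.45, and the middle 50% of rows lay between -1.47 and 1.50, against a median standard error of 0.21. This balance depended on the scale between libraries. When each library was scaled to the mean FPKM total, which multiplied nuclear values by 1.38 and cytoplasmic values by 0.784, 11875 of 26060 tested transcript rows were higher in the nucleus and 6392 in the cytoplasm. Over the 25081 rows tested at first, this scaling gave 10865 and 6476. The direction of the middle transcript row is therefore relative to the deposited scale. On that scale its log2 difference was -0.56 without nucleus replicate 1 and -0.57 without nucleus replicate 2.

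**Figure D2:**
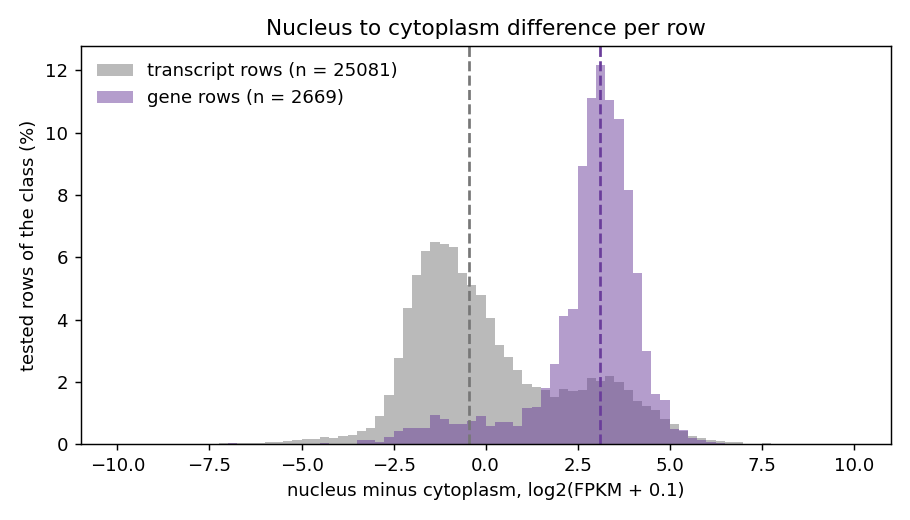
Distribution of the nucleus minus cytoplasm difference, in log2(FPKM + 0.1), as the percentage of tested rows of each class in bins of equal width, with dashed lines at the medians. Gene rows (purple) centre on 3.11, and transcript rows (grey) have their median at -0.45 with a long shoulder under the gene rows.

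The gene rows stood apart from the transcript rows in where they lay between the fractions. Their median log2 difference was 3.11, against -0.45 for transcript rows, which is 3.55 higher (camera in limma, preset correlation, p = 9.9e-38). With an estimated correlation of 0.088, camera gave p = 0.048, near the threshold of 0.05. That estimate was made for the main fit only, so whether this p holds under other settings was not tested. Centring each library on its median, the replicate block and the fit without a variance trend leave the difference at 3.55 by construction. They therefore do not test it. Within libraries, the median gene row lay 0.30 ± 0.02 log2 units below the median transcript row in the nucleus and 3.21 ± 0.06 below it in the cytoplasm (SD, n = 2). Scaling to the mean FPKM total can change the difference between the classes only through the pseudocount and the rows that pass the filter. It gave 3.21, and 3.46 over the same rows as the main fit. The difference was 2.59 with quantile normalization, 2.04 with a pseudocount of 1 and 0.57 with no filter on low values. With 10000 lists of transcript rows matched to the gene rows on mean FPKM, the list medians had a middle value of -0.01 and 0 lists reached the gene row median.

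Some rows were near the floor in one fraction and well above it in the other. Rows at 1 FPKM or more in both nuclear libraries and under 0.1 FPKM in both cytoplasmic libraries numbered 923 among transcript rows and 543 among gene rows. The reverse pattern was shown by 300 transcript rows and 1 gene row. By the same limits, a single nuclear against a single cytoplasmic library gave 2204 to 2482 nuclear and 881 to 1027 cytoplasmic transcript rows, whereas 2 replicates of a fraction gave 329 to 426. For gene rows the single-library counts were 699 to 826 for the nucleus and 3 to 9 for the cytoplasm, against 2 to 4 between replicates. With libraries scaled to the mean FPKM total and the limits left in place, so that the limits are lower for nuclear and higher for cytoplasmic RNA, 1456 transcript rows and 1429 gene rows were nuclear by these limits, and 222 and 1 were cytoplasmic.

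The transcript row with the largest nuclear excess was ENSMUST00000128220.5, at 104 ± 7.13 FPKM in the nucleus and 0.110 ± 0.156 FPKM in the cytoplasm (SD, n = 2). Its log2 difference was 9.19 with a standard error of 0.61 (limma, adjusted p = 0.00062). It was 6.57 at a pseudocount of 1 and 11.08 at 0.01, and 8.34 without cytoplasm replicate 1 and 10.03 without cytoplasm replicate 2. The transcript row with the largest cytoplasmic excess was ENSMUST00000196695.2, at 99.1 ± 3.95 FPKM in the cytoplasm and under 1e-06 FPKM in both nuclear libraries (limma, adjusted p = 0.00012). Its size depends on the pseudocount, with a log2 difference of -6.64 at a pseudocount of 1 and -13.27 at 0.01, so no fold is given. Both rows are isoform estimates, which share reads with other isoforms of their genes.

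Transcripts abundant on average over the fractions lay towards the cytoplasm. The median log2 difference of transcript rows was 0.21 at 1 to 3 FPKM, -0.38 at 3 to 10, -0.92 at 10 to 30, -1.32 at 30 to 100 and -1.61 at 100 to 300. It was -1.68 for the 124 rows of 300 to 1000 FPKM and -1.62 for the 58 rows of 1000 FPKM or more. Over the 4 pairs of a nuclear with a cytoplasmic library, the median for rows of 1 to 3 FPKM ranged from 0.20 to 0.25 and that for rows of 1000 FPKM or more from -1.61 to -1.58, so the trend was larger than the spread between replicates. Rows high in the cytoplasm enter higher groups because cytoplasmic totals are larger. After scaling to the mean FPKM total, with groups formed again, the medians were 1.04 at 1 to 3 FPKM, 0.59 at 3 to 10, 0.03 at 10 to 30, -0.39 at 30 to 100 and -0.70 at 1000 FPKM or more. Calls per group were counted on the deposited scale and its groups only. There the share of rows called higher in the cytoplasm (limma) was 24.7% at 1 to 3 FPKM and 94.8% at 1000 FPKM or more. The share called higher in the nucleus was 35.7% and 3.45% in the same groups. Across all tested transcript rows, Spearman's rho between mean FPKM and the log2 difference was -0.26, -0.33 with the mean of log2 values and -0.20 after scaling. Ranking on one fraction builds in its own direction, and rho was 0.17 when scaled rows were ranked on the nucleus alone and -0.71 on the cytoplasm alone, so the trend depends on how abundance is measured. Rows are not independent replicates and no p is given for it.

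**Figure D3:**
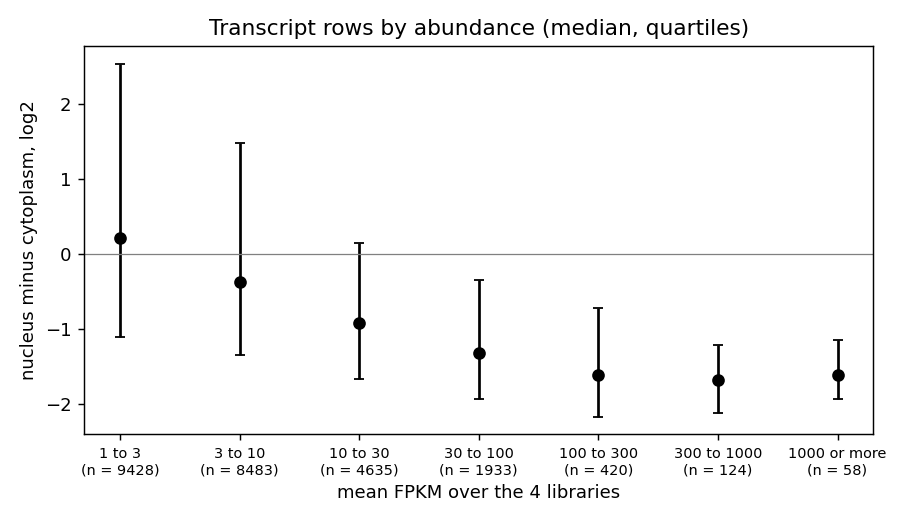
Median nucleus minus cytoplasm difference of transcript rows (log2, points) with the lower and upper quartiles (bars), by mean FPKM over the 4 libraries. The median falls from 0.21 in the scarcest group to -1.62 in the most abundant one.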

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

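The class comparison, the scaling to the mean FPKM total, the centring on transcript medians, the estimated correlation and the minimum fold for transcript rows were chosen after seeing the data. In alternatives able to change it, the class difference was 0.57 (no filter on low values) to 4.32 (mean FPKM of at least 5). It was 3.32 to 3.74 with 1 library left out. Camera p in these fits used the preset correlation. The log2 differences of the 4 rows named by identifier kept their direction and their call under each alternative, though their sizes moved with the pseudocount and the scaling. Counts of called rows moved by more than 1.5 times as follows, the filter changing also how many rows are tested. With no filter on low values, 14080 of 22719 gene rows were higher in the nucleus and 377 in the cytoplasm. With a mean FPKM of at least 5 these were 301 and 75, and 2828 transcript rows were higher in the nucleus. With each library centred on its median, gene rows gave 1050 and 805, and with quantile normalization 1134 and 774, since both set the middle of the gene rows near 0. With libraries scaled to the mean FPKM total, 98 gene rows were higher in the cytoplasm, and transcript rows gave 11875 nuclear and 6392 cytoplasmic calls. Over the same rows as in the first fit these were 103 gene rows, and 10865 and 6476 transcript rows, of which the count of 10865 stayed within 1.5 times. Leaving out 1 library gave 1729 to 3029 nuclear and 146 to 172 cytoplasmic gene rows, and 4946 to 8172 nuclear and 9341 to 10319 cytoplasmic transcript rows, with the lone library of a fraction assumed to vary like the other fraction. The abundance filter then weighs the complete fraction more. With 1 library left out, only the nuclear count of transcript rows without nucleus replicate 2 moved by more than 1.5 times. The median log2 difference of transcript rows was nevertheless alike without either nuclear library, at -0.56 without replicate 1 and -0.57 without replicate 2. With the replicate block the counts were 2447 and 162 for gene rows and 7363 and 10858 for transcript rows, and no count changed by over 1.5 times. The numbers are not stated to pair the samples, and deviations of same-numbered libraries correlated at 0.13 in gene rows and 0.01 in transcript rows. Other pseudocounts, the fit without a variance trend, the centring of gene rows on the transcript medians and a minimum of a 2-fold change kept each count within 1.5 times. The alternatives for gene lists, lncRNAs, isoforms within a gene and the most abundant isoform were not run, because the table holds no symbols, classes or parent genes. Depth is unknown, and scarce isoform estimates limit the transcript calls.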

Other observations

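Transcript rows with later Ensembl numbers lay more towards the nucleus. In the lowest-numbered 20% of tested transcript rows, 70.4% were higher in the cytoplasm and 9.83% in the nucleus (limma, adjusted p under 0.05), with a median log2 difference of -1.10. In the group of equal size numbered 135691 to 161311, the shares were 21.6% and 52.9%, and the median difference was 1.60. The 20% with the latest numbers lay between them, with a median of 0.03, so the relation was not a steady rise. Over the 4 pairs of a nuclear with a cytoplasmic library the median ranged from -1.11 to -1.09 in the lowest-numbered group and from 1.50 to 1.53 in the group from 135691. Gene rows showed the opposite order, with Spearman's rho of -0.27 between number and difference.

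The tests below were set down before their results were seen, except those of gene rows as RNA held in the nucleus and of simulated tables without a second peak, which were chosen after. For transcript rows, rho between identifier number and the nucleus minus cytoplasm difference was 0.32. Later numbers belong to scarcer transcripts (rho of -0.30 with mean FPKM), and transcripts scarce by mean FPKM over the 4 libraries lay towards the nucleus. Abundance alone, measured in this way, is argued against, since within 10 bins of mean FPKM the median rho was 0.26 and the lowest 0.12. Bins of abundance in a single fraction were not used. A candidate explanation is that later numbers hold more partial, intron-retaining or noncoding models, which stays untested because the table gives no transcript classes.

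The gene rows lay higher in the nucleus than the transcript rows. Low abundance of gene rows, taken as mean FPKM over the 4 libraries, is argued against. The gene row median lay 3.00 log2 units above the upper bound of the central 95% of transcript lists matched on that mean. Lists matched on abundance in a single fraction were not drawn, so low abundance in the cytoplasm alone is not addressed. DNA in the nuclear libraries as the whole cause would give each gene about one level per kilobase, if rows are scaled by the length that DNA reads cover. Only on that condition, which could not be checked, is it argued against. The 90th percentile of nuclear gene rows above 0.01 FPKM was 140 times the 10th, with a correlation between replicates of 0.94. Over all gene rows the nuclear median was 0.0046 and 0.0041 FPKM in the replicates. The 10th percentile was 0.020 FPKM, where scatter of scarce rows can widen the range. As a hypothesis, gene rows may follow RNA held in the nucleus such as unspliced transcripts. At least 93.0% of gene rows lay above the median transcript row under each of 4 scalings, but that restates the pattern and decides nothing, and the sources used here do not say what a gene row spans.

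Over all tested transcript rows, a second, lower peak was counted near the gene rows. Its bin held 1056 rows against 820 in the dip, the lowest bin between the peaks. The ratio was 1.29, with a 95% counting interval of 1.18 to 1.41. That ratio was not set against simulated tables. The peak was sought only in a range around the gene rows, so its place near them was set by the search. Both classes had a peak in the bin centred on a log2 difference of 3.25, and 4585 transcript rows (18.3%) lay above the lower quartile of the gene rows. Only 0.857% of the lowest-numbered 20% lay there, against 39.0% of the group numbered from 135691. Whether unsteady estimates of scarce transcripts could make this peak stays open. Among transcript rows of at least 10 FPKM with replicates within 0.5 log2 units, the peak bin held 107 rows against 78 in the dip, a ratio of 1.37 with a 95% counting interval of 1.02 to 1.84. Since the bins were picked as highest and lowest, the ratio was set against 10000 simulated tables whose counts only fall above the lower peak, which reached it with a one-sided p of 0.047. Among steady rows of any abundance the ratio was 1.05, with an interval of 0.924 to 1.196, so no peak was shown there. The bound set in advance covered only the abundant rows, which met it. In the wider set of steady rows the highest and lowest bins were other ones, centred on 2.75 and 2.25. That set neither shows nor excludes a peak.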
